A study of Phaffia rhodozyma with 6 samples.

How the data were processed

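RNA was measured by sequencing in 6 cultures of the astaxanthin-producing yeast Phaffia rhodozyma, 3 of the mutagenised strain BPAX-A1 and 3 of the wild-type strain CBS6938. Per the labels' protocols, the cultures grew on sucrose in a defined medium in fermenters held at pH 5.5, 20 °C and 70% dissolved oxygen. RNA was extracted with the ZymoBiomics DNA/RNA Miniprep Kit and libraries were made with the Illumina Stranded mRNA kit, per the labels' protocols. The submitters' processing notes name FastQC, Trimmomatic, TopHat, Cufflinks and Cuffdiff. Their versions, the genome build and the gene annotation are not given in the sources used here. Loci are therefore given on numbered scaffolds, as the authors' table has them, without exon, intron or UTR detail. Starts in the file appeared to count from 0: among 458 genes with a span under 600 bases, end minus start was a multiple of 3 in 254, with 105 and 99 at the other remainders. All printed starts are the file's start plus 1.

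The authors' deposited table holds 1 FPKM value per gene for each of the conditions that it calls q1 and q2, as Cuffdiff estimates it over the libraries of a condition. Per the file headers it also gives the log2 ratio of q2 over q1, a test statistic (a score per gene), a p-value and a q-value. The normalization between libraries is not given in the sources used here. No source used here ties q1 or q2 to a strain, so every direction below is that of q2 against q1, and none is assigned to the mutant or the wild type. The per-sample columns numbered 0, so no replicate spread, no replicate test and no depth per library could be computed. Each value stands for 1 condition of 3 cultures. Read totals per library are unknown, as are the counts behind any gene. The authors' p-values have a floor of 5e-05, reached by 139 tested genes.

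The columns were checked against each other. The log2 ratio recomputed from the FPKM values differed from the authors' deposited log2 ratio by at most 1.38e-05 over 6271 genes. Benjamini-Hochberg adjustment of the p-values over the 6272 tested genes differed from the authors' q-value by at most 5.26e-07. A second sheet repeats the left-hand columns of the first in another order, with 0 differing cells. A further sheet holds 331 genes that the authors selected. The annotation columns were used for names alone. They list 6380 proteins, of which 17 have no test and were not analysed here.

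A gene was called when the authors' q-value was below 0.05, with no minimum on the size of the change and no filter on low values. An implied standard error was computed as the absolute log2 fold change divided by the normal quantile of its two-sided p-value. It is an approximation, and none is given for a p-value at the floor. Gene lists were matched by words in the names and descriptions: carotenoid synthesis, the mevalonate pathway, sterol synthesis, glycolysis and gluconeogenesis, pyruvate and acetyl-CoA supply, the TCA and glyoxylate cycles, the pentose phosphate pathway, fatty acid synthesis and desaturation, beta-oxidation and peroxisomes, oxidative stress defence, the respiratory chain and ATP synthase, cytosolic ribosomal proteins, chaperones and heat shock, sugar uptake and sucrose use, amino acid and nitrogen uptake, metal uptake, cell wall, DNA repair, cell cycle with histones and DNA replication, proteasome and ubiquitin, cytochrome P450 and efflux, carbon catabolite repression, and RNA quality. The last of these 23 lists matched no RNA gene. From the matches, 133 entries were removed by hand as unrelated proteins, for example protein prenyltransferases among the carotenoid terms. The removals were decided with the values in view, and the lists as matched were run as an alternative.

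For each of the 22 lists with members, called genes were counted by direction and compared with the other tested genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 44 tests. This test treats genes as independent. The median of log2((q2 + 1)/(q1 + 1)) of each list, with a pseudocount of 1 FPKM, was placed among 10000 random lists of the same size matched on expression decile (10 deciles). A list is described as outside the random range when its median lay outside the central 95% of these. The percentile is a description and not a p-value. Medians cover all members of a list, tested or not. Random lists were drawn from all genes of a decile, list members and ribosomal protein genes included. Ribosomal protein genes were mostly higher in q2 and highly expressed, which may raise the random range for lists of highly expressed genes. The highest decile has no upper limit, so matching there is coarse. Counts adjusted over the list alone used the authors' p-values of the list's own members after the removals by hand. They were not made for the lists as matched. Bootstrap SDs used 1000 draws.

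The genes named are those of a rule. It takes the members of the carotenoid, mevalonate and sterol lists, at most 12 per list, and up to 4 called members of each other list by absolute log2 fold change. It adds the 10 highest and the 10 lowest log2 fold changes among called, described genes with both values above 0 and the higher value at least 5 FPKM. It also takes the 3 highest values in each condition and up to 4 described genes listed at 0 in 1 condition. It gave 77 genes. The list terms, the naming rule, the tests and a first set of alternative settings were fixed before the data were examined. A list of 12 mitochondrially encoded genes, a list of light-related names, the split by scaffold size and all further tests in the closing section were chosen after the values were seen. No name in the annotation matched the term mitochondrially encoded, so the assignment of these 12 genes was made here.

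The alternative settings of that first set were a q-value below 0.01, an absolute log2 fold change of at least 1, a higher value of at least 1 FPKM, leaving out values of 0, adjustment again after the filter, pseudocounts of 0.1 and 5 FPKM, medians over genes of at least 5 FPKM, and centring of log2 ratios on the median of genes above 1 FPKM in both conditions. Added after the values were seen were the lists as matched, the lists without mitochondrially encoded genes, calls without genes on scaffolds of at most 3 genes, and centred list medians.

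The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with the random seed 7. The calculation was run on simulated data with 6254 genes, of which 200 changed. Calls at q below 0.05 recovered 10% of 50 genes changed by a log2 of 1, 64% of 50 at 2, 90% of 50 at 3 and 94% of 50 at 4. Of the calls, 3.01% were unchanged genes. A planted list had an adjusted p of 3.37e-12, and 0 of 20 random lists passed the threshold. The planted list held genes given a rise and the random lists only unchanged genes, so both outcomes were largely set by the design. Simulated genes were independent, and their p-values used the standard errors that generated them. The run therefore checks the calculation, and not Cuffdiff's p-values or lists of genes that vary together. A list shifted by 1 had a median of 0.91 at percentile 100.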

Results

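The series compares the transcriptome of the mutagenised, astaxanthin-overproducing yeast strain BPAX-A1 with that of the wild-type strain CBS6938 in late exponential phase, from 3 fermenter cultures of each. The question was which transcripts differ between the strains during the phase of fastest astaxanthin formation. The authors' deposited table holds 1 FPKM value per gene and condition, over the replicates, for 6363 genes. The conditions are called q1 and q2, and which of them is the mutant is not given in the sources used here. All directions are therefore those of q2 relative to q1. With 1 value per condition, no spread between replicates can be given, and the depth of each library is unknown. A standard error implied by the authors' p-value is given where the p-value is above its floor. It restates Cuffdiff's test and does not measure the spread between cultures. All FPKM values, log2 fold changes, p-values and q-values of single genes come from the authors' deposited table.

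In the authors' deposited table, 6272 genes were tested, 88 had too little signal and 3 had too much signal for a test. Of the tested genes, 347 (5.53%) had a q-value below 0.05, 229 of them higher and 118 lower in q2. At an unadjusted p below 0.05 there were 916 genes, 657 higher and 259 lower. The called genes had a median absolute log2 fold change of 2.30, and the smallest was 1.32, a 2.51-fold change. The median implied standard error was 0.51 on the log2 scale over 6124 genes. The highest q-value among the called genes was 0.0488, and the lowest among the others was 0.0503. Of the called genes, 204 had a description and 143 had none. The median log2 ratio of the 6106 genes above 1 FPKM in both conditions was 0.11, and list medians are given both as they stand and relative to this shift. The FPKM values summed to 1030220 in q1 and 2161510 in q2, a ratio of 2.10, while the median gene had 38.2 FPKM in q1 and 45.1 in q2. The 10 highest genes held 10.9% of the sum in q1 and 19.1% in q2.

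**Figure D1:**
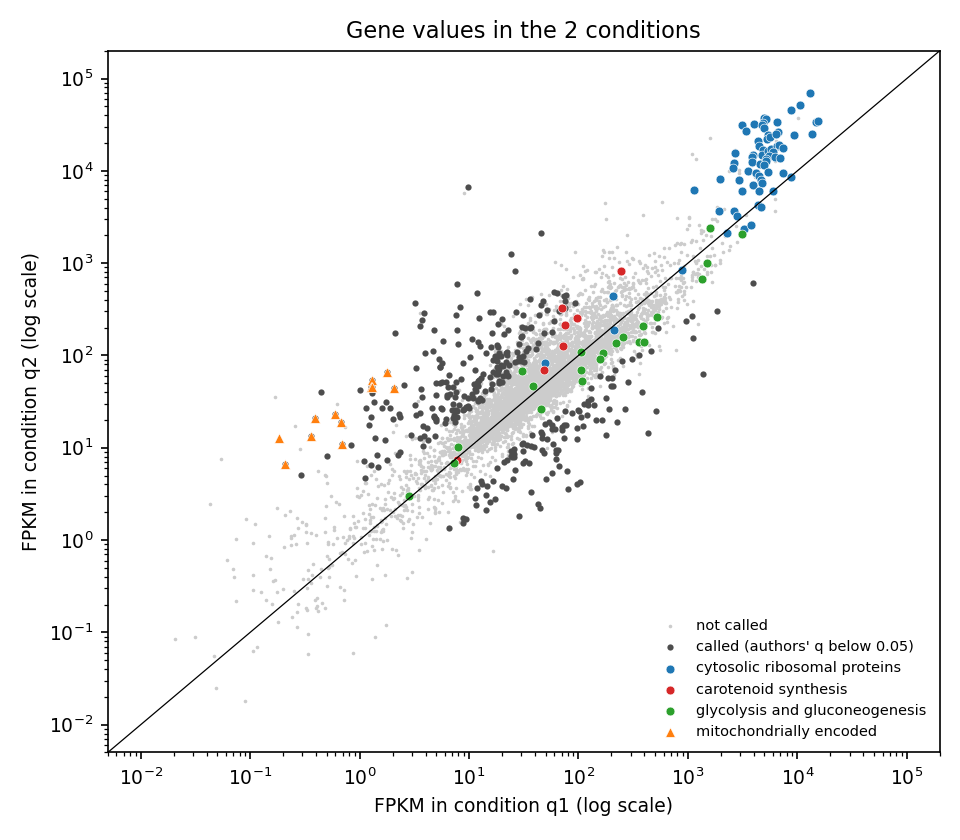
FPKM in q2 against q1 on log axes for genes with both values above 0, light grey where not called and dark grey where called. Coloured points mark the ribosomal protein, carotenoid and glycolysis lists. Triangles mark all 12 mitochondrially encoded genes, called or not. The 229 genes called higher include 11 mitochondrially encoded genes with q1 values of at most 2.06 FPKM.

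The highest log2 fold change among called and described genes was that of Conidiation-specific protein 6 (CED85080, scaffold 249, 455828 to 456255). In the authors' deposited table it had 9.75 FPKM in q1 and 6660 in q2, a 683-fold difference (log2 9.42, q 0.00226). A glutathione S-transferase (CED84930, scaffold 249, 6619 to 7695) had 0.440 and 39.7 FPKM, a log2 fold change of 6.50 with an implied standard error of 1.71. With a pseudocount of 1 FPKM its log2 ratio was 4.82. A further glutathione S-transferase (CDZ97957), on the short scaffold 185, rose from 1.0 to 41.9 FPKM (log2 5.39, or 4.42 with that pseudocount). An oligopeptide transporter of the OPT superfamily (CED85432) had 3.75 FPKM in q1 and 243 in q2 (log2 6.02). A short-chain dehydrogenase (CDZ96711) had 3.54 and 209 FPKM (log2 5.89). The KEKE-like motif-containing transcription regulator Rlr1 (CED85283) had 24.4 and 1255 FPKM, a log2 fold change of 5.69 with an implied standard error of 1.84 and a q-value of 0.0386. A photolyase/cryptochrome (CED82658, scaffold 33, 2068733 to 2071114) had 11.9 and 479 FPKM, a log2 fold change of 5.34 with an implied standard error of 1.41. The other 3 of the 10 highest were mitochondrially encoded subunits of the respiratory chain.

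The lowest log2 fold change among called and described genes was -4.59, for a lysyl hydrolase/glycosyltransferase family 25 gene (CDZ98154, scaffold 242, 109580 to 111004). Its value in the authors' deposited table was 102 FPKM in q1 and 4.23 in q2, 24.1-fold lower (q 0.00226). A glycoside hydrolase of family 16 (CED82980) had 96.8 and 4.10 FPKM (log2 -4.56), and one of family 3 (CED83962) had 224 and 19.1 FPKM (log2 -3.55). The UspA gene (CED83073, scaffold 52, 1224483 to 1226236) went from 509 FPKM in q1 to 24.8 in q2, 20.6-fold lower. An alpha beta-hydrolase (CED85434) had a log2 fold change of -3.78, and a gene described only as alcohol (CDZ96436) one of -3.70. A heat shock transcription factor (CDZ96670) had 37.2 FPKM in q1 and 3.35 in q2, 11.1-fold lower. A ferric reductase (CED82645) and the adjacent FAS1 domain gene (CED82646) had log2 fold changes of -3.46 and -3.45. The TauD/TfdA dioxygenase gene (CED82966) went from 383 to 39.9 FPKM (log2 -3.26).

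Whether the carotenoid route itself differed was addressed with 7 genes, none of them called by Cuffdiff over all genes. By the authors' p-values, 1 was higher when adjusted over the list alone, and 2 were higher and 0 lower at an unadjusted p below 0.05. The count over the list alone rests on the 7 genes left after removals made with the values in view. It was not made over the 12 genes as matched. The highest was an astaxanthin synthase (CED83940, scaffold 69, 1230024 to 1233189), with 71.3 FPKM in q1 and 328 in q2 in the authors' deposited table. Its log2 fold change was 2.20 with an implied standard error of 0.81 (p 0.00685, q 0.0957). Phytoene dehydrogenase (CED83513) had 243 and 821 FPKM, a log2 fold change of 1.76 with an implied standard error of 1.04 (q 0.452). The phytoene-beta carotene synthase gene (CED83449) had 75.6 and 215 FPKM (log2 1.51, implied standard error 0.82, q 0.389). Geranylgeranyl pyrophosphate synthase (CDZ97186) had 96.5 and 254 FPKM (log2 1.40, implied standard error 0.62, q 0.213). A further polyprenyl synthetase (CED82684) had a log2 fold change of 0.81, a phytoene/squalene synthetase (CED85288) one of 0.53, and another gene named astaxanthin synthase (CED83052) one of -0.07. The list median was 1.39, or 1.28 relative to the shift of all genes, at percentile 98.6 of random lists matched on expression. With the 5 protein prenyltransferases that the search terms also match, the median of 12 genes was 0.67, which lay inside the random range.

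The 7 mevalonate pathway genes all had lower values in q2, and none was called by Cuffdiff (0 at an unadjusted p below 0.05). Removing the shift of all genes, which is upward, could not reverse these signs. Their log2 fold changes in the authors' deposited table ran from -0.06 for hydroxymethylglutaryl-CoA reductase (CED85502, 42.0 and 40.2 FPKM) to -0.86 for hydroxymethylglutaryl-CoA synthase (CED83016, 162 and 89.0 FPKM). The latter had an implied standard error of 0.61 and a q-value of 0.560, the smallest of the list. Isopentenyl pyrophosphate isomerase (CED82414) had 239 and 156 FPKM (log2 -0.62), phosphomevalonate kinase (CDZ97430) a log2 fold change of -0.51, and diphosphomevalonate decarboxylase (CED83492) one of -0.32. Mevalonate kinase (CED82307) stood at -0.20 and farnesyl pyrophosphate synthase (CDZ96456) at -0.20. Members of the list had a median of -0.32, or -0.43 relative to the shift, at percentile 8.68 and inside the random range. With nothing removed from the matches, the median of 9 genes was -0.20, at percentile 11.2.

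Of the 11 sterol synthesis genes, 0 were called by Cuffdiff and 1 was lower at an unadjusted p below 0.05. That gene was a c-4 methyl sterol oxidase (CDZ96809), with 24.6 FPKM in q1 and 11.0 in q2 in the authors' deposited table (log2 -1.16, implied standard error 0.45, q 0.126). The other c-4 methyl sterol oxidase (CED83720) had a log2 fold change of 0.22, squalene epoxidase (CED83144) 0.52, lanosterol synthase (CED82918) -0.77 and lanosterol demethylase (CED84182) -0.44. The sterol O-acyltransferase gene (CDZ96511) stood at -0.57, C-3 sterol dehydrogenase (CED83486) at -0.11, the C-8,7 sterol isomerase (CED84918) at 0.29 and a sterol-regulatory metalloprotease (CED83298) at 0.32. A sterol reductase (CED83197) stood at 0.07 and at -0.04 after centring. The phytoene/squalene synthetase (CED85288, log2 0.53) is a member of this list as well as of the carotenoid list. The list median of 0.07, at percentile 42.9, likewise became -0.04 relative to the shift.

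**Figure D2:**
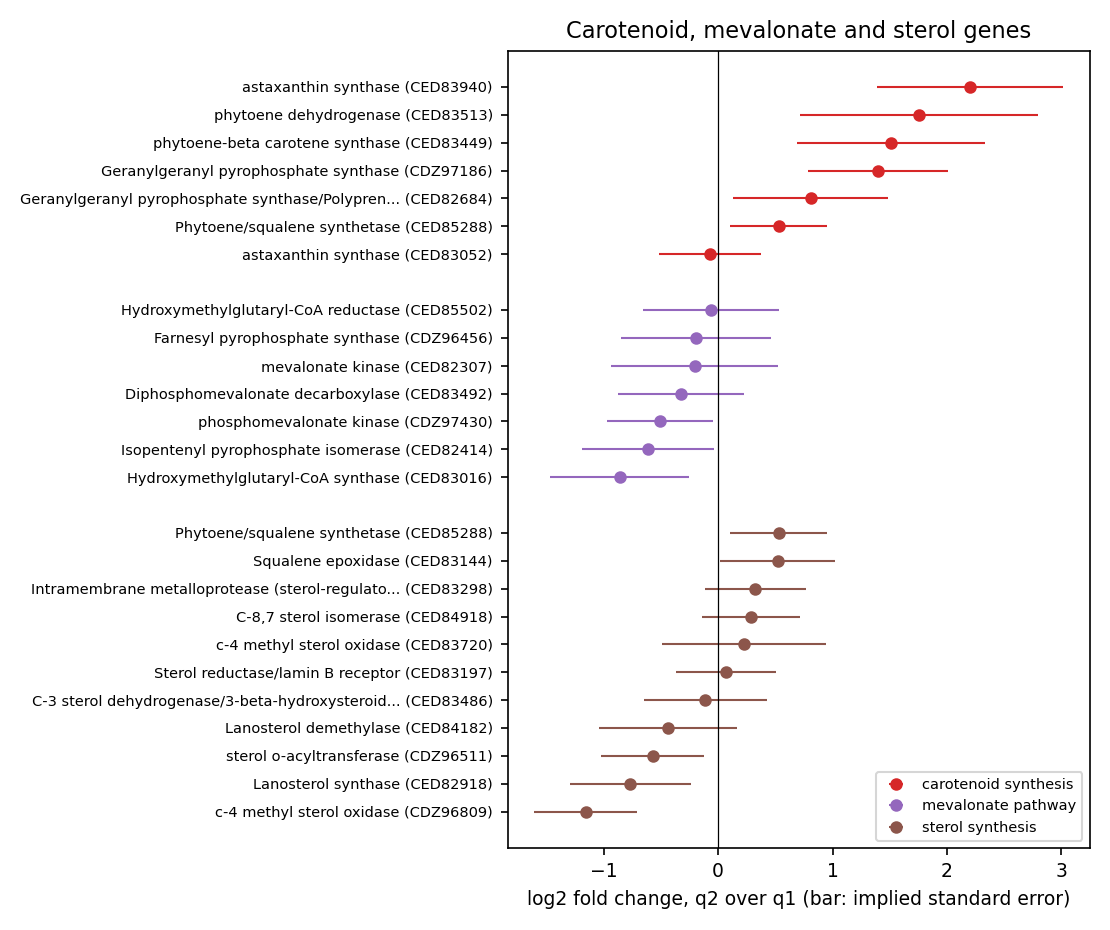
Log2 fold change of q2 over q1 for the genes of the carotenoid, mevalonate and sterol lists, with bars of 1 implied standard error. Of the 7 carotenoid genes, 6 lie above 0, all 7 mevalonate genes lie below 0, and none of the genes was called. The phytoene/squalene synthetase (CED85288) belongs to both the carotenoid and the sterol list and is drawn in each.

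In glycolysis and gluconeogenesis, 0 of 21 genes were called by Cuffdiff and 1 was higher at an unadjusted p below 0.05. Values were lower in q2 for 15 of the 21 genes, and for 17 after centring. The median of -0.65, or -0.76 relative to the shift, was lower than in any of the 10000 random lists. These were drawn from all genes of a decile, including ribosomal protein genes, most of which had higher values in q2. Random lists without ribosomal protein genes were not run. Examples chosen after their values were seen, from the authors' deposited table, are glucose-6-phosphate isomerase (CED83630, 399.6 and 141 FPKM, log2 -1.51), hexokinase (CED82858, log2 -1.36) and glyceraldehyde-3-phosphate dehydrogenase (CED85376, 3135 and 2094 FPKM, log2 -0.58). For pyruvate and acetyl-CoA supply, 1 of 17 genes was called, the class V alcohol dehydrogenase (CDZ98236). Its value fell from 86.4 to 23.9 FPKM in the authors' deposited table (log2 -1.85, implied standard error 0.50, q 0.00705). Adjusted over the list alone, 1 gene was higher and 2 were lower. The median over the list was -0.54, or -0.65 relative to the shift, at percentile 0.02, but with the 6 related dehydrogenases and regulators that the terms also match it was -0.01, with 2 of the 23 genes called higher. Pyruvate decarboxylase (CED83333, 156 and 46.3 FPKM, log2 -1.76, q 0.111) and ATP-citrate synthase (CED83572, log2 -1.41), also chosen after their values were seen, were not called in the authors' deposited table.

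For the TCA and glyoxylate cycles, 1 of 22 genes was called, a malate dehydrogenase (CED83303) with 12.9 and 4.31 FPKM in the authors' deposited table (log2 -1.58, q 0.0210). On adjustment over the list alone, 2 genes were lower. The median of this list was -0.31, or -0.42 relative to the shift, at percentile 0.82. The lower edge of its random range was -0.23, from random lists that likewise could hold ribosomal protein genes. All 6 pentose phosphate genes had lower values in q2, which centring could not reverse, with 0 called by Cuffdiff and 0 at an unadjusted p below 0.05. Their median was -0.55, or -0.67 relative to the shift, at percentile 4.41. Transaldolase (CED82849), chosen after its value was seen, had 1655 FPKM in q1 and 627 in q2 in the authors' deposited table (log2 -1.40). Among 9 genes of fatty acid synthesis and desaturation, Cuffdiff called 0, 1 was higher at an unadjusted p below 0.05, and the median was -0.46, or -0.57 relative to the shift, at percentile 3.76. Among 22 genes of beta-oxidation and peroxisomes, the enoyl-CoA hydratase/isomerase (CED84218) was called, with 30.4 and 11.1 FPKM in the authors' deposited table (log2 -1.46, q 0.0488). The median there was 0.15, or 0.04 relative to the shift, at percentile 63.2. By adjustment over the list alone, 1 of these genes was higher and 1 lower. Neither gene of the carbon catabolite repression list was called by Cuffdiff, with 0 at an unadjusted p below 0.05, and their median was -0.47, or -0.58 relative to the shift, at percentile 11.2. With the creatinase that the search terms also match, the median of 3 genes was -0.02, at percentile 37.6.

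The 3 highest values in each condition were those of cytosolic ribosomal protein genes. Over the 73 genes of this list the median was 4756 FPKM in q1 and 13974 in q2, and they held 36.3% of the FPKM sum in q1 and 56.1% in q2. Values were higher in q2 for 65 of the 73, and for 64 after centring. The list median was 1.41, or 1.30 relative to the shift, at percentile 100, though matching by decile is coarse at such high values. Cuffdiff called 0 of them, with 3 higher and 0 lower at an unadjusted p below 0.05, and the median implied standard error was 1.54, against 0.51 over the tested genes. The highest value in q2 was that of 40S ribosomal protein S25 (CED84866, scaffold 78, 1562329 to 1563365), with 12924 and 69307 FPKM in the authors' deposited table (log2 2.42, implied standard error 1.60, q 0.521). It was followed by 40S ribosomal protein S30 (CED82514, 10671 and 51647 FPKM) and 60S acidic ribosomal protein P2 (CDZ97054, 8804 and 45182 FPKM). The highest values in q1 of the authors' deposited table were those of 60S ribosomal protein L37a (CED84867, 15520 and 34760 FPKM), the ubiquitin-S31 fusion (CDZ96411, 14791 and 33534 FPKM) and 60S ribosomal protein L37 (CDZ98073, 13733 and 25377 FPKM).

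Of the 108 tested genes of the proteasome and ubiquitin list, 1 was called, a predicted E3 ubiquitin ligase (CED83815). It had 12.4 FPKM in q1 and 252 in q2 in the authors' deposited table (log2 4.34, q 0.00226). At an unadjusted p below 0.05, 9 were higher and 1 lower. Members of the list had a median of 0.39, or 0.28 relative to the shift, at percentile 99.9.

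The respiratory chain and ATP synthase list was the only list past the threshold of the Fisher tests. Of its 62 genes, 9 were called higher where 2.26 were expected, and 0 were called lower (Fisher's exact p 3.69e-04, adjusted p 0.0162). All 9 belong to the genes taken here as mitochondrially encoded, 10 of which are members of the list. Cuffdiff called 0 of the other 52 members, of which 3 were higher and 1 lower at an unadjusted p below 0.05. The median over the list was 0.30, or 0.19 relative to the shift, at percentile 84.6, and without the mitochondrially encoded members it was 0.13. At an unadjusted p below 0.05, 13 genes of the whole list were higher and 1 lower. At a q-value below 0.01, 4 of its genes were called and the adjusted p was 0.559. Adjusted over the list alone, 9 were higher and 1 lower. Of 12 mitochondrially encoded genes in the table, a group formed after the values were seen, 11 were called higher, with a median log2 fold change of 5.18 over the 12 and a range of 4.0 to 6.10. With a pseudocount of 1 FPKM the log2 ratios of the 12 ran from 2.67 to 4.59. Their values were 0.185 to 2.06 FPKM in q1 and 6.71 to 65.5 FPKM in q2. In the authors' deposited table, cytochrome c oxidase subunit 1 (CED80056, scaffold 22, 404 to 2280) had 1.29 FPKM in q1 and 54.4 in q2 (log2 5.39, implied standard error 1.47). Subunit 2 (CDZ96152, log2 5.30) and subunit 3 (CED80061, log2 5.22) were called as well. So was a gene described as NADH dehydrogenase subunits 2, 5 and related proteins (CDZ96153, log2 5.76). The table held 0 genes of rRNA or tRNA, so the share of such RNA in the libraries could not be read.

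Among the 58 tested genes of oxidative stress defence, 3 were called higher and 1 lower. The called genes were both glutathione S-transferases given above, catalase 1 (CDZ96425) and, lower in q2, a gene with a thioredoxin-like fold (CED85166). In the authors' deposited table, catalase 1 had 31.4 FPKM in q1 and 272 in q2 (log2 3.12, implied standard error 0.91, q 0.0180). The thioredoxin-like gene had 120 and 22.7 FPKM (log2 -2.41). The median over all 60 members was -0.11, or -0.22 relative to the shift, at percentile 2.48. At an unadjusted p below 0.05, 6 genes were higher and 4 lower. Of 53 chaperone and heat shock genes, 4 were called higher and 1 lower. Besides the heat shock transcription factor, the authors' deposited table had a DnaJ chaperone (CDZ96732) at 28.9 and 134 FPKM (log2 2.21), another (CED83818) at a log2 fold change of 1.80, and a predicted heat-shock lipase (CDZ98595) at 1.45. The list median was 0.35, or 0.24 relative to the shift, at percentile 95.3.

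DNA repair genes had higher values in q2 for 50 of 63, and for 45 after centring. Called were 5, all higher, where 2.30 were expected (Fisher's exact adjusted p 0.87), and at an unadjusted p below 0.05 there were 9 higher and 0 lower. Members of the list had a median of 0.33, or 0.22 relative to the shift, at percentile 99.6. Besides the photolyase above, another photolyase/cryptochrome (CDZ97756) had 6.67 FPKM in q1 and 38.5 in q2 in the authors' deposited table (log2 2.53). The postreplication repair gene RAD18 (CED84714, scaffold 78, 1088352 to 1090512) had 16.1 and 177 FPKM (log2 3.46, implied standard error 1.11, q 0.0369). An ATP-dependent DNA helicase (CDZ96565) had 18.8 and 107 FPKM (log2 2.51). In the list of cell cycle, histones and DNA replication, 3 of 63 tested genes were called, all higher. They were the catalytic subunit of DNA polymerase zeta (CDZ96255, 3.80 and 17.3 FPKM, log2 2.19), DNA polymerase IV (CDZ97716, log2 1.92) and replication factor C subunit RFC1 (CED84456, log2 1.81) in the authors' deposited table. The median over all 67 members was 0.00, or -0.11 relative to the shift, at percentile 10.4. It falls on untested members, whose values do not differ between the conditions. Over the 60 members with a higher value of at least 5 FPKM the median was -0.04, at percentile 5.6.

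Among 36 tested genes of cytochrome P450 and efflux, 5 were called higher where 1.31 were expected, and 1 was called lower (Fisher's exact p 0.00929 for the higher genes, adjusted p 0.204). Adjusted over the list alone, 7 were higher and 1 lower. In the authors' deposited table a multidrug resistance protein (CED83097) had 1.35 FPKM in q1 and 31.1 in q2 (log2 4.53). A cytochrome P450 of the CYP3/CYP5/CYP6/CYP9 subfamilies (CED84998) had 7.91 and 131 FPKM (log2 4.05), and an ABC transporter (CED82131) 12.5 and 126 FPKM (log2 3.33). A P450 of the CYP2 subfamily (CED85015) was lower, at 14.2 and 3.07 FPKM (log2 -2.21). The median over the list was 0.47, or 0.36 relative to the shift, at percentile 99.7. With a pseudocount of 5 FPKM it was 0.28, and over the 29 genes of at least 5 FPKM it was 0.68.

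For amino acid, ammonium and nitrogen uptake, 2 of 28 tested genes were called higher and 3 lower (Fisher's exact p 0.0151 for the lower genes, adjusted p 0.221). Adjusted over the list alone, 4 were higher and 3 lower. The called genes included the OPT transporter above and another oligopeptide transporter (CDZ97625, 2.28 and 23.0 FPKM, log2 3.33) in the authors' deposited table. An ammonium transporter (CED83532) had 105 and 21.7 FPKM (log2 -2.28), and an amino acid transporter (CED84839) 14.3 and 2.11 FPKM (log2 -2.76). The list median of 0.05 became -0.06 relative to the shift, at percentile 35.6. In metal uptake and homeostasis, the copper transporter (CED82663) was called higher, at 7.65 and 39.8 FPKM in the authors' deposited table (log2 2.38), and the ferric reductase given above (50.7 and 4.62 FPKM) was called lower, out of 23 genes. The median of this list was -0.05, or -0.16 relative to the shift, at percentile 13.4. With the 8 metal-dependent enzymes that the search terms also match, the median of 31 genes was 0.09, at percentile 41.5, and 3 were called higher and 1 lower. Of 12 genes of sugar uptake and sucrose use, a sugar transporter (CED83916) was called, at 12.6 and 34.5 FPKM in the authors' deposited table (log2 1.45, q 0.0409), and the median of 0.05 became -0.06 relative to the shift, at percentile 38.0. With the acetyltransferase that the search terms also match, the median of 13 genes was -0.04. Cuffdiff called 0 of 30 cell wall genes, with 2 higher and 0 lower at an unadjusted p below 0.05, and their median was -0.11, or -0.22 relative to the shift, at percentile 2.49. Over the 29 of them with a higher value of at least 5 FPKM the median was -0.19, at percentile 0.33. With the glycogen branching enzyme that the search terms also match, the median of 31 genes was -0.03, at percentile 10.6 and inside the random range.

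**Figure D3:**
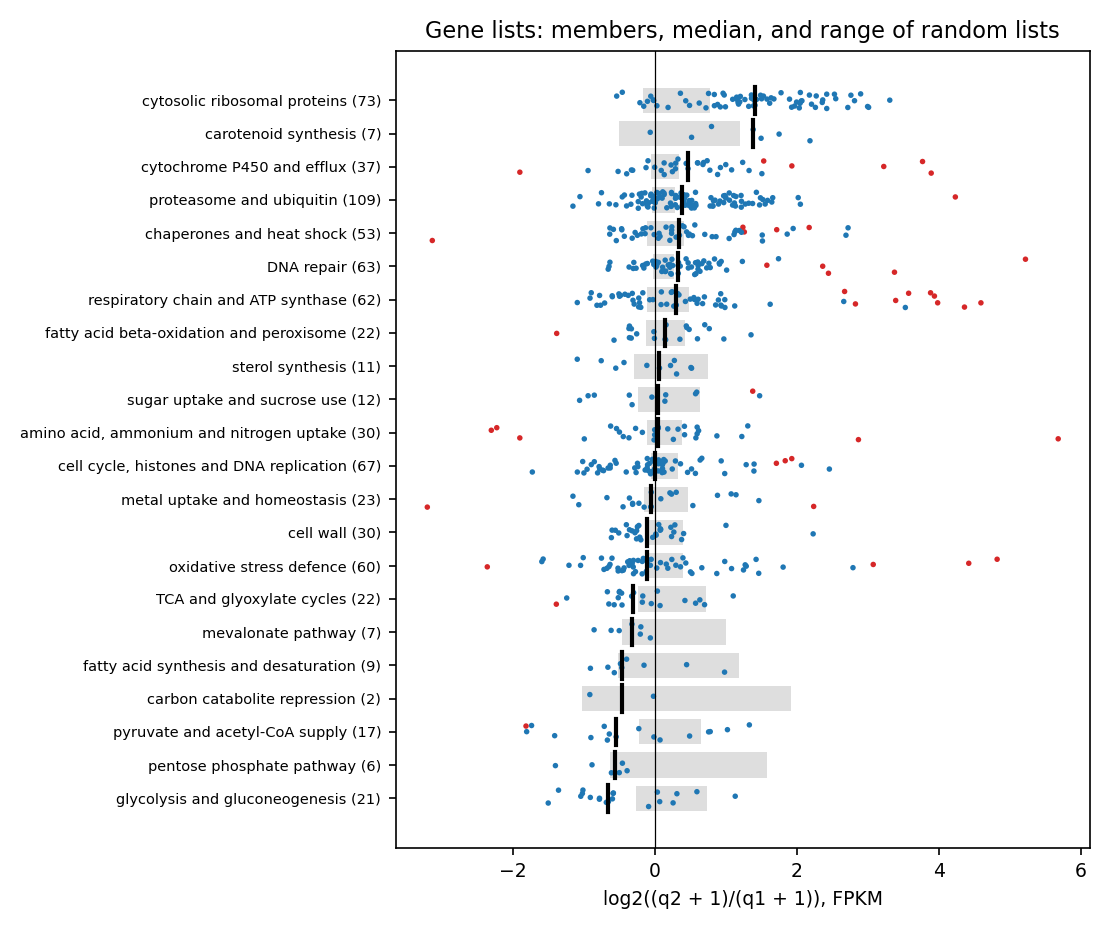
Log2 ratio of q2 over q1, with a pseudocount of 1 FPKM, for the genes of each list. Points are single genes, red where called and blue where not, black bars are list medians and grey bands are the central 95% of medians of random lists matched on expression. The medians of 10 of 22 lists lie outside their band, the highest being that of the ribosomal proteins at 1.41 and the lowest that of glycolysis at -0.65. Those of oxidative stress defence (percentile 2.48) and the cell wall (percentile 2.49) lie only just past the lower edge of theirs.

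Over the lists together, 44 of 739 genes were called, 34 higher and 10 lower in q2. Adjusted over the list alone, the counts equalled those over all genes in each direction for all lists but the carotenoid, pyruvate, TCA, beta-oxidation, respiratory, nitrogen and P450 lists, whose counts are given above. Values of 0 were listed for 83 genes in q1 and 68 in q2, of which 59 were at 0 in both. Of the called genes, 13 were listed at 0 in q1 and 3 in q2, none of them with a description. The described genes listed at 0 in 1 condition were a gag-pol polyprotein (CDZ98543, 0.00832 FPKM in q2) and a MAPEG family gene (CDZ97457, 0.0347 FPKM in q1) in the authors' deposited table, and neither had enough signal for a test. The authors' selected sheet held 331 genes, 216 higher and 115 lower, all of them among the called genes. The 16 called genes left off that sheet were the ones listed at 0 in 1 condition.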

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

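The lists as matched, the runs without mitochondrially encoded genes or short scaffolds, and the centred list medians were chosen after the values were seen. At a q-value below 0.01, 192 genes were called, 129 higher and 63 lower in q2 (67.2% higher), all among the 347, and 27 genes of the lists. The respiratory list then had 4 called genes and an adjusted Fisher p of 0.559. Without its mitochondrially encoded genes it had 0 called by Cuffdiff of 52 and an adjusted p of 1. With the lists as matched its adjusted p was 0.0341, against 0.0162 in the main setting. A stricter threshold calls fewer genes by construction. A minimum absolute log2 fold change of 1 and centring could not change the calls or the Fisher tests, since the smallest called change was 1.32 and centring moves it by 0.11, so they say nothing about stability. The total was 342 with at least 1 FPKM and with adjustment again after that filter, 331 without values of 0, and 325 (209 higher, 116 lower) without short scaffolds. Centring by 0.11 gave medians of -0.22 for oxidative stress, 1.30 for ribosomal proteins, 0.22 for DNA repair and 0.28 for the proteasome. It reversed the sterol reductase CED83197, to -0.043, and kept the sign of the other 74 named genes tested. The P450 and efflux median was 0.28 with a pseudocount of 5 FPKM and 0.68 over genes of at least 5 FPKM; the cause was not tested. With nothing removed from the matches, the carotenoid median was 0.67 (12 genes, percentile 96.6, inside the random range), that for pyruvate and acetyl-CoA -0.011 (23 genes), that for the cell wall -0.028 (31 genes, percentile 10.6), both inside the range too, that for carbon catabolite repression -0.017 (3 genes), those for metal uptake (0.087) and sugar uptake (-0.040) changed sign, and 7 lists lay outside the range, against 10 under the other alternatives for medians, of which centring shifts the random lists alike. Here the added genes are the cause by construction. No paired analysis was possible because the table has no values per sample. For the same reason leaving out each replicate, a replicate block, edgeR, DESeq2, limma with another pseudocount and other splits of the samples were not run. Depth is unknown, so what it limits cannot be given.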

Other observations

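All tests here were chosen after the results were seen. Genes with light-related names were called higher more often than other genes, 4 of 14 against 225 of 6258 other tested genes (Fisher's exact p 0.00130, not adjusted), with 1 called lower. The names were picked because the photolyase and Conidiation-specific protein 6 stood out, so this p-value cannot be taken as evidence. The genes called higher were Conidiation-specific protein 6 (CED85080), the photolyases CED82658 and CDZ97756, and a BLUF domain protein (CED85203, log2 1.55, q 0.0353, chosen after its value was seen). A Velvet factor (CED85626, log2 -1.66, q 0.0057) was called lower. The other 9 were not called. They include white collar 1 (CDZ96450, log2 0.81), a rhodopsin (CDZ98620, log2 1.71, q 0.0756) and relatives of the called genes that did not follow them: another Conidiation-specific protein 6 (CED85109, log2 -0.68), a photolyase (CED82716, 0.59), 3 BLUF genes (0.09, -0.09 and -0.30) and 2 Velvet factors (0.10 and -0.36). A candidate explanation is a difference in light exposure or light response between the conditions, which the labels do not record and which was not tested.

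Called genes of 1 direction lay side by side on the scaffolds in 18 pairs, 9 higher and 9 lower. Random placement of the calls gave 10.4 on average (p 0.0174, 0.0348 after Benjamini-Hochberg adjustment over this test and that of scaffold ends). None of the 18 pairs had overlapping loci. The random mean was the same with overlapping neighbours left out, so hardly any neighbours overlap and this excludes little. A pair, cytochrome b (CED80058) with apocytochrome b (CED80059) on the short scaffold 176, is mitochondrially encoded. These entries (449 to 949 and 1043 to 1615) may be parts of 1 gene, which was not tested and would lower the mitochondrial gene counts. Without the mitochondrially encoded genes there were 17 pairs against 9.71 by chance (p 0.0179). Neighbours called in opposite directions numbered 7, against 8.54 by chance (p 0.748). Pairs chosen after their values were seen are the ferric reductase with the FAS1 gene, the amino acid transporter CED84839 with a glycoside hydrolase (CED84840, log2 -2.10), and polymerase zeta with an EF-hand gene (CDZ96256, log2 2.58). Clusters of genes under shared control may account for the excess among the 17, which was not tested further. Within 50 kb of the outermost genes of the 15 long scaffolds, 38 of 522 tested genes (7.28%) were called, against 287 of 5662 (5.07%) elsewhere on them (Fisher's exact p 0.0395, also after adjustment). This test treats genes as independent, while called genes lay side by side more often than under random placement. Its p-value may therefore be too small and is no firm evidence.

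Transcripts of the 12 mitochondrially encoded genes were higher in q2 by a median log2 of 5.18. Small values in q1 alone do not account for this. The median lay at percentile 100 of random sets drawn from 204 other genes with q1 values in the same range. Those genes had a median of 0.57, and the highest set reached 3.23. With a pseudocount of 1 FPKM the ratios of the 12 genes were smaller, with log2 values of 2.67 to 4.59. The 46 other tested genes on scaffolds of at most 3 genes, 39 higher and 7 lower in value, also had a higher median. It was 2.57 (bootstrap SD 0.56) when the 5 listed at 0 in q1 rank as the highest, against 0.11 on longer scaffolds. Over the 41 with both values above 0 the median was 2.25. The lowest mitochondrial value of 4.0 was reached or passed by 12 of the 46, those 5 included. The median of the 46 lies below that value by more than its bootstrap SD, so a rise of all short-scaffold genes alike does not account for the whole difference, but part of it may be shared. A different carry-over of RNA without long poly(A) tails remains open, because the table had 0 rRNA or tRNA genes, and so do a different match of each strain's reads to the reference and a biological difference between the strains, both untested.

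The 46 genes on short scaffolds divide into 39 higher and 7 lower in q2, with 9 called higher and 2 lower, and 41 have no description. Their highest values are large: CDZ98108 had 1576 FPKM in q1 and 22729 in q2 (log2 3.85, q 0.133), CDZ97954 1195 and 13357, and CDZ96629 174 and 4470 in the authors' deposited table. These genes were chosen after their values were seen.

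Ribosomal protein transcripts were higher in q2 by a median log2 of 1.41 (bootstrap SD over genes 0.11). None of the 73 was called by Cuffdiff, 3 were higher at an unadjusted p below 0.05, and the median implied standard error of a single gene, 1.54, exceeds the shift, so the difference is one of values over the list and not of called genes. Random sets of other genes with the same locus lengths had a median of 0.11, and sets matched on length and expression 0.60, with an upper limit of 0.87 over 72 members and as few as 7 genes to draw from. The median over all genes was 0.11. Locus length or a common scale factor therefore do not account for the whole difference. Matching on length and expression takes up part of it. The highest expression class in that matching had no upper limit, so the ribosomal genes could be set against far less expressed genes. An effect that rises with expression therefore remains open. Locus length is the genomic span, so transcript length could not be matched and remains open. The random sets and the bootstrap run over genes and not over cultures, so variation between cultures remains open too. A difference in growth rate between the strains is untested, and the strain behind q2 is not given in the sources used here.

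Few highly expressed genes were called: among genes with both values above 0, 7.0% of those with a change of at least 2-fold in the highest expression decile, against 32.7% in decile 5. Over the other deciles this share ran from 16.02% in decile 9 to 51.4% in decile 2, with 18.4% in decile 1. Smaller changes do not account for this, since the median absolute log2 fold change among the genes changed by at least 2-fold was 1.71 in the highest decile (258 genes, bootstrap SD 0.07) and 1.43 in decile 5 (104 genes, bootstrap SD 0.06). Of those at or above the smallest called change of 1.32, 9.47% of 190 and 57.6% of 59 were called. The median implied standard error was 0.82 in the highest decile and 0.49 in decile 5, but it is derived from the same p-values as the calls and so restates the pattern. A larger spread at high expression, between the cultures or in Cuffdiff's model, remains open without values per sample.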
